A study of Mus musculus with 13 samples.

How the data were processed

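The series profiled chromatin in mouse embryonic fibroblasts by chromatin immunoprecipitation and sequencing. Lentivirus was used to express histone H3.1 or H3.3 with lysine 27 changed to methionine (K27M) or to arginine (K27R), and control cells are labelled as empty. The labels describe 13 samples in 11 groups: H3K27me3, EZH2 and combined FLAG and EZH2 immunoprecipitations. H3K27me3 is the trimethyl mark that the Polycomb repressive complex PRC2 places on histone H3, and EZH2 is the catalytic subunit of that complex. Per the labels' protocols, cells were crosslinked with formaldehyde, chromatin was cut to mononucleosomes with micrococcal nuclease, and precipitated DNA was made into sequencing libraries.

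Processed files were analysed for 2 samples only, the first replicate of H3K27me3 in H3.1K27M cells and of H3K27me3 in H3.3K27M cells. Each is a list of peaks. The label of the second replicate of each group names the same peak list, so each group of 2 replicates is represented by 1 list, and no label says whether reads of both were pooled. The K27R, EZH2, FLAG and empty-vector samples were not analysed here. For 2 of them, the EZH2 samples of H3.1K27R and H3.3K27R cells, the genotype label reads H3.1K27M although the title and source name read K27R. These samples entered no comparison.

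Per the submitters' processing notes, reads were aligned to the mouse build mm9 with Bowtie 1.0.0, and deepTools was used. The peak caller, its threshold and any input correction are not given in the sources used here. The deposited lists hold, for each peak, a chromosome, a start, an end, a width in bp and a running name. They hold no height, fold enrichment or p-value, so the lists could not be ranked by signal, and the sequencing depth behind a peak is unknown. In the deposited lists every start lies on a 200 bp grid, so widths are resolved to that step. Running numbers follow position but skip: they reach 1079 in the H3.1K27M list with 26 numbers unused, and 1247 in the H3.3K27M list with 55 unused. Why these numbers are unused is not given in the sources used here. A peak list also depends on the depth and threshold of its library: a deeper library or a more permissive threshold gives more and wider peaks from the same chromatin. No label gives a spike-in or a common depth, and presence or width of a peak was therefore not read as an amount of H3K27me3.

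Positions were read as BED intervals and are printed with the first base counted as 1, on mm9. Peaks were counted as shared when they overlapped by at least 1 bp. Peaks of both lists connected by such overlaps formed a region. Shares of peaks carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only and treat peaks as independent. The overlap was set against 10000 placements of each peak at random on its own chromosome, a one-sided permutation test whose smallest possible p is 0.0001. Widths were compared in regions holding exactly 1 peak of each list, as the log2 ratio of the H3.3K27M width to the H3.1K27M width. The mean log2 ratio was tested by a two-sided sign-flip permutation over regions (100000 draws, smallest possible p 1e-05). The median carries a bootstrap interval (10000 draws). The chromosomes of peaks without a partner were compared by permuting the list label over those peaks (100000 draws). The same label was also permuted over runs of neighbouring peaks of one list. The length of the longest such run was set against random orders of the regions within each chromosome (10000 draws). Single chromosomes were compared by Fisher's exact test with Benjamini-Hochberg adjustment. Peak densities per Mb carry Poisson intervals. Regions are not replicate cultures, so each p-value compares these 2 lists and not the conditions.

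Most regions described were chosen by a rule fixed before the data were examined: the 10 widest shared regions, the 5 widest regions of each list without a partner, and the 5 stretches of up to 500 kb with the most peaks of both lists. The run of peaks at the end of chromosome 7, the part of chromosome 17 with 3 and 2 peaks, the narrowest peaks and a stretch tied for the last place were added after the data were seen. Planned comparisons of peaks with transcription start sites and with gene lists (Hox genes, other homeobox genes, other developmental transcription factors, signalling genes, cell cycle inhibitors, fibroblast genes, housekeeping genes, genes of other lineages and imprinted genes) were not run, because the gene table used here describes a later mouse assembly and coordinates were not carried over between builds. Genes are therefore not named. Alternatives covered the overlap rule, the merging of peaks under 5 kb apart, the wider peaks only, the sex chromosomes and the random placement.

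Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and networkx 3.6.1, and mm9 chromosome lengths came from GenomeInfoDb 1.38.1 in R 4.3.3. The procedure was tested on simulated data with 1000 peaks per list, of which 700 were common and 1.3 times wider in one list. It recovered 700 common peaks and a width ratio of 1.3, and the overlap of unrelated simulated lists gave p = 0.0609 by permutation. Simulated peaks were kept well apart, and common peaks had the same start in both lists, so recovery was easy. Clustered peaks, split peaks and runs of peaks were not tested in this way.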

Results

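H3K27me3 was mapped in mouse embryonic fibroblasts that stably expressed the lysine-to-methionine mutant of either of 2 histone H3 forms. H3.1 is the form deposited mainly during DNA replication, and H3.3 is deposited throughout the cell cycle. Each mutant had 2 replicate samples under 1 deposited peak list. The comparison between the lists addressed where the mark was called in cells carrying each mutant. With a single list per group there was no spread between replicates, and all tests below treat peaks or regions as units. Tests chosen after results were seen were the moves of up to 1 Mb, the test of the imbalance between regions with several peaks of one list, the tests of peak densities and of single chromosomes, the run on chromosome 7, and the permutation over runs and the reciprocal overlap for chromosome shares.

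In both mutants H3K27me3 was called over a small part of the genome in broad peaks. The H3.1K27M list held 1053 peaks that covered 8.75 Mb, or 0.331% of the assembled autosomes and X chromosome. The H3.3K27M list held 1192 peaks over 11.9 Mb, or 0.45%. The H3.3K27M list thus had 1.13 times as many peaks and 1.36 times the covered length. Peaks had a median width of 5.6 kb in H3.1K27M cells (quartiles 3.4 and 9.6 kb, largest 82.2 kb) and 7.2 kb in H3.3K27M cells (quartiles 4.6 and 11.2 kb, largest 102.4 kb). No peak was called on the Y chromosome in either list.

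The 2 mutants largely shared the places where H3K27me3 was called. Of the H3.1K27M peaks, 855 (81.2%, 95% exact interval 78.7 to 83.5%) overlapped an H3.3K27M peak. In the other direction 838 of the H3.3K27M peaks (70.3%, interval 67.6 to 72.9%) overlapped an H3.1K27M peak. By length, 84.9% of the sequence covered in H3.1K27M cells lay inside H3.3K27M peaks, while 62.6% of the sequence covered in H3.3K27M cells lay inside H3.1K27M peaks. The lists had 7.42 Mb in common, 56.3% of the 13.2 Mb covered by either. Random placement of the H3.1K27M peaks on their chromosomes gave 10.2 ± 3.17 overlapping peaks (SD over 10000 placements, highest 22), so the observed number was 83.7 times the random mean (permutation p = 0.0001, the smallest these placements allow). Placing the H3.3K27M peaks at random gave 10.1 ± 3.16 overlapping peaks and an excess of 82.9 times (permutation p = 0.0001). When each peak was only moved by up to 1 Mb, which keeps the regional crowding of peaks, the excess was 25.2 times for H3.1K27M and 24.7 times for H3.3K27M, each with permutation p = 0.0001. With a reciprocal overlap of 50% required in place of 1 bp, the excess was 394.5 and 405.6 times. The shares of peaks with a partner fell to 66.1% and 58.4% under this rule. The larger excess therefore reflects fewer random overlaps and not closer agreement of the lists.

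Peaks joined into 1383 regions, of which 831 were shared, 198 were found in the H3.1K27M list only and 354 in the H3.3K27M list only. Most shared regions, 807, held 1 peak of each list. In 17 regions a single H3.3K27M peak overlapped 2 or more H3.1K27M peaks, up to 4, and in 7 regions a single H3.1K27M peak overlapped 2 H3.3K27M peaks. This imbalance did not pass the threshold (exact binomial p = 0.0639, two-sided).

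Where both mutants had a single peak, the H3.3K27M peak was usually the wider one. Median widths over these 807 regions were 6.2 kb in H3.1K27M cells and 8.2 kb in H3.3K27M cells. The median log2 width ratio was 0.33 (95% bootstrap interval 0.30 to 0.36), a 1.25-fold difference. The mean log2 ratio was 0.36 (sign-flip permutation p = 1e-05, two-sided, the smallest possible). The ratio varied between regions, with an SD of 0.60 on the log2 scale. H3.3K27M peaks were wider in 627 regions (77.7%), H3.1K27M peaks in 157 (19.5%), and the widths were equal in 23. The H3.3K27M peak reached beyond the H3.1K27M peak at both edges in 495 regions, and the reverse held in 53. The median extension was 0.8 kb at the left edge and 0.8 kb at the right edge. On all 20 chromosomes with peaks the median log2 ratio was above 0, from 0.14 on chromosome 15 to 0.70 on the X chromosome.

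**Figure D1:**
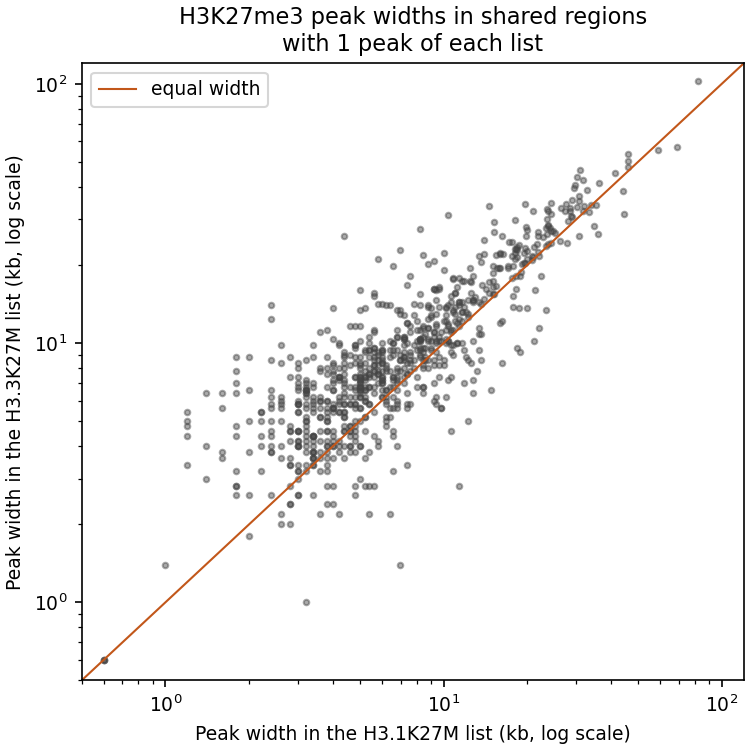
Each point is 1 of the 807 shared regions with 1 peak of each list, with the H3K27me3 peak width in H3.1K27M cells (kb, log scale) on the x axis and in H3.3K27M cells (kb, log scale) on the y axis; the line marks equal width. Of these points, 627 lie above the line and 157 below it.

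The broadest shared domain lay on chromosome 15 from 102726001 to 102828399 (mm9), where 1 H3.1K27M peak of 82.2 kb lay within 1 H3.3K27M peak of 102.4 kb. The next, on chromosome 2 from 74481601 to 74553199, was wider in H3.1K27M cells, with 68.8 kb against 57 kb. On chromosome 7 from 86639001 to 86706399, 3 H3.1K27M peaks totalling 53.2 kb faced a single H3.3K27M peak of 67.4 kb. A similar domain on chromosome 9, from 91243201 to 91306199, had 3 H3.1K27M peaks with 49 kb in all against 1 H3.3K27M peak of 63 kb. On chromosome 4 from 115598601 to 115656199 the H3.1K27M list had 4 peaks with 35.6 kb in all and the H3.3K27M list 1 peak of 57.6 kb, a ratio of 1.62. The remaining 5 of the 10 broadest shared domains lay on chromosomes 19 (3 domains), 11 and 4, with ratios of H3.3K27M to H3.1K27M covered length from 0.83 to 1.16. In this group of 10 the H3.1K27M list covered more in 4 domains. None of these ratios has a replicate check.

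Peaks called in a single mutant were narrower than shared ones in both lists. H3.1K27M peaks without a partner had a median width of 3.2 kb against 6.2 kb for those with one, a log2 difference of -0.95. H3.3K27M peaks without a partner had a median of 5 kb against 8.4 kb, a log2 difference of -0.75. Both differences passed a two-sided permutation test (p = 1e-05 for each, the smallest possible). Exceptions in width were 24 H3.1K27M and 57 H3.3K27M peaks without a partner that were wider than the median peak with one in their own list. Peaks without a partner made up 8.79% of the covered length in H3.1K27M cells and 17.9% in H3.3K27M cells.

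The widest domains of the H3.3K27M list with no H3.1K27M peak lay on chromosome 11 from 96106601 to 96145199 (38.6 kb), chromosome 3 from 128896001 to 128933999 (38 kb) and chromosome 1 from 122487201 to 122523799 (36.6 kb). They were followed by chromosome 6 from 6804601 to 6827199 (22.6 kb) and chromosome 13 from 99120001 to 99139999 (20 kb). The domain on chromosome 11 lay 30.2 kb from a shared domain of 53.6 kb, which ran from 96022801 to 96076399. The other 4 lay at least 244 kb from the nearest shared region. In the H3.1K27M list the widest domains with no H3.3K27M peak lay on chromosome 8 from 125224801 to 125247399 (22.6 kb) and on chromosome 17 from 36292601 to 36308799 (16.2 kb) and from 36313801 to 36327399 (13.6 kb). They were followed by chromosome 16 from 91167401 to 91179199 (11.8 kb) and chromosome 12 from 88322401 to 88333799 (11.4 kb). The chromosome 8 domain lay 4.4 kb from a shared region, and the 2 on chromosome 17 lay at least 683.6 kb from one. The chromosome 17 pair faced a place in the H3.3K27M list where 2 running peak numbers are unused. The other 8 domains named here faced no unused number in the other list.

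The distal end of chromosome 7, singled out after its values were seen, carried H3K27me3 peaks in the H3.3K27M list alone. From 144512401 to 152087999 there were 19 neighbouring H3.3K27M peaks, 147 kb in all and up to 19.8 kb wide, and no H3.1K27M peak. The last H3.1K27M peak of the chromosome ended at 139793799, which left 12.7 Mb without one. On the rest of the chromosome 45 of 61 H3.3K27M peaks (73.8%) had a partner. The next longest run of peaks from a single list held 4 peaks. Random order of the regions within each chromosome gave runs of at most 13 in 10000 draws (permutation p = 0.0001, the smallest possible). These draws take regions as independent, while some peaks of the run lay close together, so this p-value may be too small. The run held 19 of the 35 H3.3K27M peaks of chromosome 7 without a partner.

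**Figure D2:**
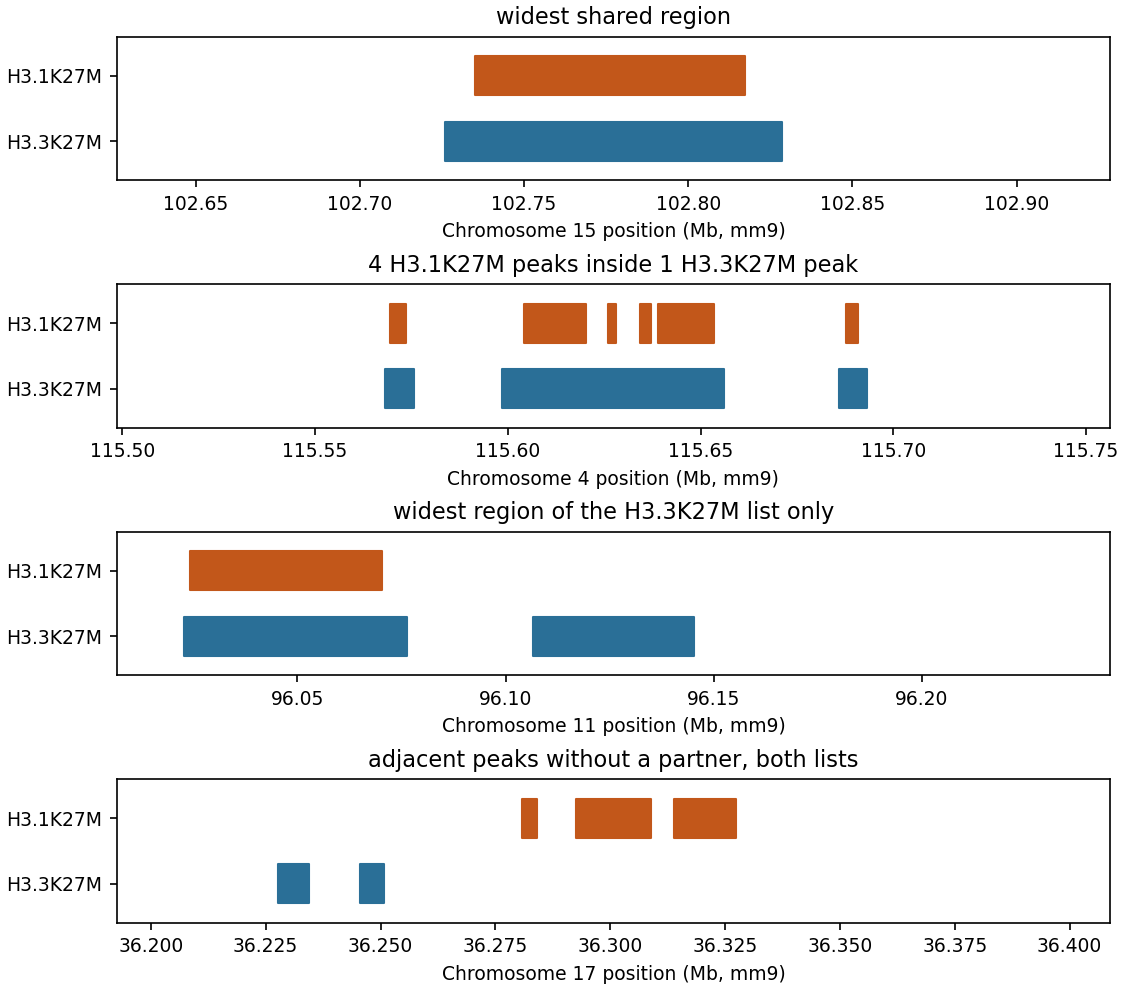
Deposited H3K27me3 peaks (filled bars) in H3.1K27M cells (upper track of each panel) and H3.3K27M cells (lower track) along 4 regions, with mm9 position in Mb on the x axis. The panels show the widest shared region on chromosome 15, the chromosome 4 region with 4 H3.1K27M peaks against 1 H3.3K27M peak, the 38.6 kb chromosome 11 domain of the H3.3K27M list only, and a part of chromosome 17, picked after its values were seen, where 3 H3.1K27M peaks and 2 H3.3K27M peaks, 30 kb apart, all lack a partner.

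H3K27me3 peaks were unevenly spread over the genome, and both mutants showed this. In H3.1K27M cells the density was 0.706 peaks per Mb on chromosome 11 (95% Poisson interval 0.565 to 0.872) and 0.685 on chromosome 19 (0.493 to 0.925), against 0.399 over all chromosomes. It was 0.163 on chromosome 3 (0.106 to 0.239) and 0.108 on the X chromosome (0.064 to 0.171). In H3.3K27M cells chromosome 19 had 0.88 peaks per Mb (0.661 to 1.15), chromosome 11 had 0.845 (0.69 to 1.02) and the X chromosome 0.168 (0.112 to 0.243), against 0.452 over all chromosomes. Assigning peaks to chromosomes in proportion to length gave a smaller chi-square in all 100000 draws for each list (permutation p = 1e-05). Peaks lie in clusters, so these p-values and intervals take them as more independent than they are.

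**Figure D3:**
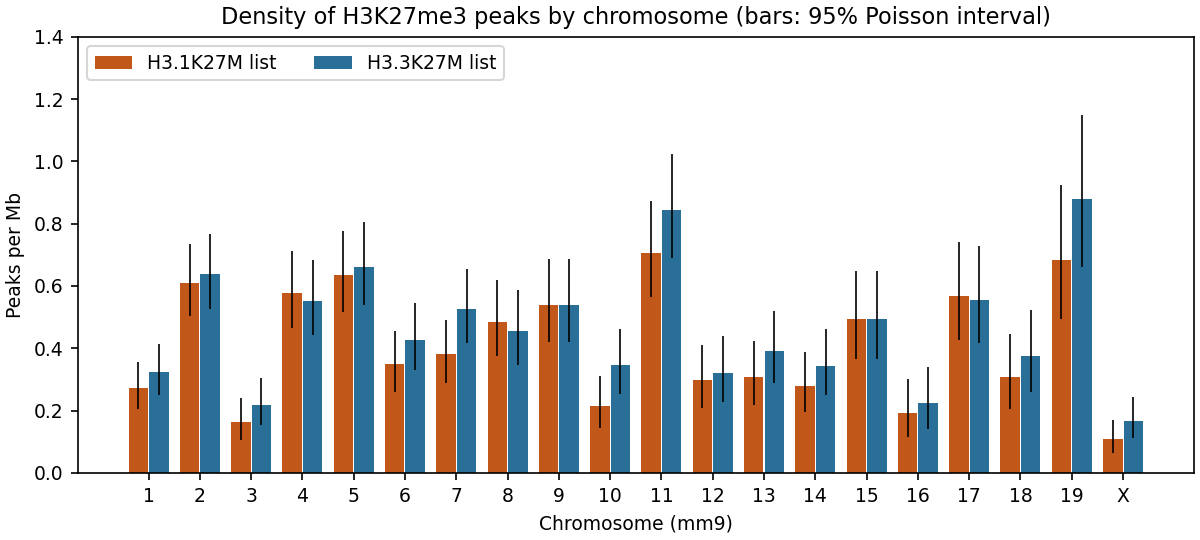
H3K27me3 peaks per Mb of each mm9 chromosome (x axis) in the H3.1K27M list and the H3.3K27M list; bars start at 0 and error bars are 95% Poisson intervals, which cover counting error only. Chromosomes 11 and 19 have the highest densities and the X chromosome the lowest in both lists.

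The most crowded stretch lay on chromosome 19 from 44705201 to 45183199, with 6 H3.1K27M peaks over 177.2 kb and 10 H3.3K27M peaks over 178 kb. On chromosome 5, from 120728601 to 121165399, there were 9 H3.1K27M peaks (58 kb) and 4 H3.3K27M peaks (47.8 kb). The next stretches were on chromosome 7 from 51590201 to 51862999 (7 and 6 peaks), chromosome 11 from 103506801 to 104000799 (6 and 6 peaks) and chromosome 2 from 164772601 to 165081599 (7 and 5 peaks). A stretch on chromosome 2 from 180505801 to 180950199 (7 and 5 peaks) held as many peaks as the last 2.

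The 2 lists placed their peaks without a partner on somewhat different chromosomes, but the difference passed the threshold in only some of the tests. The chromosome shares of the 198 H3.1K27M and the 354 H3.3K27M peaks differed by a total variation of 26.1% (permutation p = 6e-05 with the list label permuted over single peaks). Permuting the label over runs of neighbouring peaks of one list gave permutation p = 0.097. These runs are defined by the list label itself, so this p-value cannot tell a chromosome difference from clustering of peaks. Chromosome 10 had 2 H3.1K27M and 21 H3.3K27M peaks without a partner, and chromosome 8 had 18 and 13. No single chromosome passed the adjusted threshold: 2 had an unadjusted p under 0.05, and the lowest adjusted p was 0.0748 on chromosome 10 (Fisher's exact test, Benjamini-Hochberg over 20 chromosomes). With a reciprocal overlap of 50% required for a shared peak, the total variation was 14.8% and the difference no longer passed (permutation p = 0.085).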

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

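Some settings were added after seeing the data. They were the wider peaks against the whole other list, placement between the outermost peaks of a chromosome, and moves of up to 1 Mb. Also added then were the unused numbers, the run on chromosome 7, the merging and X chromosome settings for widths, and the merging of the widest domains. For the chromosome shares, all settings except the overlap of 1 bp were added then. The 4 settings of the start site and gene list comparisons were not run, for want of an mm9 annotation in the sources used here. No paired analysis was possible because each group has a single peak list, and for the same reason no replicate could be left out. Requiring a reciprocal overlap of 50% lowered the share of H3.1K27M peaks with a partner to 66.1% and of H3.3K27M peaks to 58.4%, and brought the total variation of chromosome shares to 14.8% (permutation p = 0.085), past the threshold no longer. By construction this rule also counts some overlapping peaks as unshared, namely those of strongly unequal width or offset from each other. Using only the wider peaks of each list, as planned, left the shares at 80.8% for H3.1K27M and 70.4% for H3.3K27M. Testing only the peaks at or above the median width of a list against the whole other list raised the shares to 92.5% for H3.1K27M and 84.9% for H3.3K27M. Leaving out the 13 peaks of each list that face a running number unused in the other list gave shares of 82.2% and 71.1% and a total variation of 25.9% (permutation p = 0.00028). With the list label permuted over runs of neighbouring peaks, the total variation of 26.1% no longer passed the threshold (permutation p = 0.097), nor did the 24.0% left without the run on chromosome 7 (permutation p = 0.109). Without that run the label permuted over single peaks gave permutation p = 0.00141, and 71.4% of H3.3K27M peaks had a partner. In all, 45 values of the lists as a whole under other settings kept their side of the threshold or moved little. Among them the median log2 width ratio lay between 0.27 and 0.33, each with sign-flip permutation p = 1e-05 for the mean. For the 10 widest shared domains, merging peaks under 5 kb apart reversed no ratio of covered lengths and moved 4. The ratio went to 1.11 on chromosome 9, 1.21 on chromosome 7, and 1.54 and 0.89 on chromosome 4. The unknown depth of the libraries limits every statement about a peak being absent from a list.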

Other observations

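The tests of domain size groups, chromosome densities, the X chromosome, the run on chromosome 7, the unused peak numbers, the narrowest peaks, the group of peaks on chromosome 17, the moved peaks and the bound of 50% on peaks near shared regions were chosen after the result was seen, as was the permutation of the list label over runs in the parts above. Some shared H3K27me3 domains lay close together: 157 of the 831 shared regions (18.9%, exact interval 16.3 to 21.7%) had another shared region within 50 kb. This share was not set against random placement. The median width difference between the lists had the same direction in each of 4 groups by domain size. Single-peak regions were put into 4 groups by the mean of their log2 widths. In the group with the narrowest peaks, the median log2 ratio of H3.3K27M to H3.1K27M width was 0.41 (bootstrap interval 0.28 to 0.53, 202 regions). It was 0.46 (0.39 to 0.50) in the second, 0.29 (0.20 to 0.34) in the third and 0.24 (0.19 to 0.29) in the group with the broadest peaks, above 11.4 kb. That last group reached 91.7 kb, and several of the widest shared domains were covered more in the H3.1K27M list. On the X chromosome the H3.3K27M peak was wider in 15 of 15 regions, with a median log2 ratio of 0.70 against 0.32 on the autosomes (792 regions, two-sided permutation p = 0.0114, not adjusted). The X chromosome had the highest median of the 20 chromosomes and was singled out after this was seen. Autosomes came close, with 22 of 22 regions on chromosome 3 and 21 of 22 on chromosome 10. The lowest share was 26 of 39, on chromosome 15. Only 10 peaks had the same start and end in both lists. These included all 3 of the 599 bp peaks of the H3.3K27M list, the narrowest there, on chromosome 6 from 49186201, chromosome 7 from 137977801 and chromosome 11 from 89092401. On chromosome 17, between 36227601 and 36327399, 3 H3.1K27M peaks and 2 H3.3K27M peaks lay side by side without overlap. Across the 20 chromosomes the median log2 width ratio fell as the density of shared regions rose, with Spearman rho -0.59 (permutation p = 0.00742, adjusted 0.0148 over 2 relations) and Pearson r -0.56 (p = 0.0101, adjusted 0.0202). Without chromosomes 19 and 11, the 2 farthest from the median density, these were -0.65 and -0.70 (permutation p = 0.0048 and 0.00126, not adjusted). Neither this relation nor the other one below was among the planned comparisons. Each chromosome counted equally, although its median rested on 13 to 85 regions. The X chromosome had both the lowest density of shared regions (0.09 per Mb) and the highest median log2 ratio (0.70, from 15 regions). The relation was not tested without the X chromosome and may lean on it. The other relation, of the H3.1K27M share of peaks without a partner with that density, gave rho 0.44 (p = 0.0543, adjusted 0.0543) and r 0.35 (p = 0.124, adjusted 0.124), neither of which passed. Without the same 2 chromosomes it gave 0.70 and 0.73 and did pass (permutation p = 0.00159 and 0.00087, not adjusted), so this call hangs on them.

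The first pattern was the greater width of H3.3K27M peaks in shared regions. Different joining of neighbouring called peaks is argued against as the whole cause. The median log2 ratio was 0.33 (0.30 to 0.36) in regions with 1 peak of each list, where no called peaks were joined differently. Joining with stretches that were not called in the H3.1K27M list cannot be seen in these lists and stays open. More permissive calling or greater depth in the H3.3K27M list may account for it and was not decided by these tables. The smaller share of H3.1K27M peaks without a partner, 18.8% against 29.7%, follows from the list sizes, because nearly all shared regions hold 1 peak of each. An effect of the histone variant that carries the mutation cannot be told apart from depth and calling, because there is 1 list per group and no depth is given.

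The second pattern was the peaks without a partner. Outgrowth from shared regions within 50 kb is argued against as the main cause only in that most of these peaks lay farther away. Only 12.4% of these H3.3K27M peaks (exact interval 9.18 to 16.3%) and 21.2% of the H3.1K27M peaks (15.7 to 27.6%) lay that near one. The bound of 50% for a main cause was set after these shares were seen. Outgrowth that touches a shared region counts as part of it and was not covered. By the comparison planned first, the H3.3K27M share was below the 18.9% among shared regions (odds ratio 0.61, Fisher's exact p = 0.00673). For H3.1K27M the odds ratio was 1.16 (Fisher's exact p = 0.483), which met neither planned outcome and left this list undecided. Some shared regions also lie near one another, for which no random share was computed, so the planned comparison does not decide alone. Outgrowth stays open for a smaller part, as moving each peak by up to 1 Mb left 7.31% and 10.6% as near (permutation p = 0.0001 and 0.0002). Clustering of marked sites could also give this excess. Peaks dropped from the other list after numbering are argued against as the main cause too, since no unused number can match at least 94.4% of the H3.1K27M and 96.9% of the H3.3K27M peaks without a partner, but stay open for the chromosome 17 pair, where the H3.3K27M list skips 2 numbers. Near misses at the calling limit stay open: the peaks were narrower than those with a partner, by median log2 widths of -0.95 in the H3.1K27M and -0.75 in the H3.3K27M list (permutation p = 1e-05 each; -0.81 without the run on chromosome 7), as planned for this explanation, but the lists hold no height, so narrow peaks were not shown to be weak, and 24 H3.1K27M and 57 H3.3K27M peaks were wider than the median with a partner.

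The third pattern was the run of 19 H3.3K27M peaks at the end of chromosome 7. Scattered near misses at the calling limit are argued against, as random order within chromosomes gave no run as long (permutation p = 0.0001). That order takes regions as independent, so near misses that come in clusters were not covered. Peaks dropped from the H3.1K27M list after numbering are argued against as well, since 0 running numbers are unused there. A segment missing from the H3.1K27M cells or reads, by loss of the distal chromosome or in processing before the peaks were numbered, stays open, because the 0 H3.1K27M peaks there are what defines the run and test nothing, and no read counts were analysed. An effect of the histone variant is an untested alternative.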
